A study of Mus musculus with 18 samples.

How the data were processed

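RNA was measured on 18 Affymetrix arrays, 1 array per sample, from 6 groups of 3 mouse samples. Per the labels' protocols, total RNA was extracted with a column kit, labelled with biotin through the Affymetrix whole-transcript kit and hybridised to arrays of a single platform. The groups were read from the sample titles: intestinal epithelial cells and intestinal tumours of male and of female mice, each with floxed Stat3 alleles as the control or with Stat3 deleted in the intestinal epithelium by a Cre recombinase under the Villin promoter. The replicate numbers 1 to 18 in the titles are unique over the series, so they pair no samples. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. They give no sex, age or Apc genotype for the epithelial cells and no scan date or batch for any array.

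The values analysed are the deposited log2 expression values, 1 column per array. Per the submitters' processing notes, the arrays were processed with RMA, which corrects background, normalises between arrays by quantiles and summarises probes to probe sets. The version of RMA, the array library and whether the 18 arrays were processed in a single run are not given in the sources used here. The log2 scale follows from the values, which range from 1.33 to 14.6 over 35556 probe sets, with array medians between 5.88 and 6.07. Signal over background was not given per probe set, so the number of arrays limits the precision and dim genes cannot be told from background.

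Probe sets were named through the platform table given with the data. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and were not named, and 12146 were not listed. Of those with 1 symbol, 21698 matched a current gene record by gene identifier, and the symbol changed for 0 of them. The 999 genes with more than 1 such probe set were represented by the probe set with the highest mean over the 18 arrays, which left 19938 genes. Genes were tested when they exceeded the array's 25th percentile of all probe sets in at least 3 arrays, which kept 17316 genes. No genome coordinates were used.

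The values were tested as they were, in limma 3.58.1 with R 4.3.3. A linear model with a mean for each of the 6 groups was fitted to all 18 arrays, so that the groups shared 1 estimate of the spread. The moderated statistics used an intensity trend, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 within each of 8 comparisons. These were Stat3 deletion in epithelial cells, in male tumours, in female tumours and in tumours of both sexes as the mean of the pair of sex-specific differences, the difference of the deletion effect between the sexes and between tumours and epithelial cells, tumours against epithelial cells in control mice, and male against female tumours averaged over genotypes. A difference is given on the log2 scale as the deleted group minus the control group, tumour minus epithelial cells, or male minus female, with its standard error where printed. The difference between the sexes is the female effect minus the male effect, and that between tissues is the tumour effect minus the epithelial effect.

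For gene groups, 38 lists of pathway genes, epithelial cell types, other cell types of the gut wall, gut segments and handling stress were tested with camera at its preset correlation between genes of 0.01, for lists with at least 5 measured members, which were 37. Each list was also tested with a correlation estimated from the data, and with fry, which tests whether the members move on balance in 1 direction and compares them with no other genes. Counts of list members that passed are given over all tested genes and, in places, adjusted over the list alone. Single-array checks used principal components, the mean correlation of each array with its own group, and sex-linked genes.

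The samples' groups, the tests, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named Stat3 and sex-linked genes, for each comparison the 8 largest rises and the 8 largest falls among genes that passed and whose arrays did not overlap between the groups (without the overlap condition for differences of effects, and without symbols that are only clone or model numbers), and the 5 genes with the smallest p in each direction where fewer than 5 passed. It also named up to 4 members of each list that was called or had at least 3 members that passed, and any member of the STAT3 and cell adhesion lists. A gene named outside this rule is given as chosen after its values were seen. The genes followed through the alternatives were those of the first part of this rule and, chosen after seeing the data, up to 5 members of each list that passed; list members named without passing were not followed.

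The alternatives were quantile normalisation of the deposited values, centring of each array on its median, no filter on dim genes and a stricter filter, all probe sets tested without choosing 1 per gene, robust variance, no intensity trend, array quality weights, only the compared groups in the fit, and leaving out each array in turn. Leaving out control tumour replicates 9 and 15 together, and list tests without replicates 9 and 15, without replicate 8 or without replicate 4, were chosen after seeing the data. The fits were tested on simulated data with each gene's own mean and residual spread and 200 changed genes among 17316. Values were drawn independently for each gene and array. Each gene had the same spread in every group. The simulation thus held no correlation between genes, no arrays that stand apart and no difference in spread between groups, and it checks the fits only for data without these. In the epithelial cell comparison, 71% of genes changed 2-fold and 98% of genes changed 4-fold were recovered, with 4 false calls among 173. In the tumours of both sexes the shares were 88% and 98%, with 10 false calls among 196, and in tumours against epithelial cells they were 76% and 96%, with 9 false calls among 181. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.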

Results

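Expression was measured in intestinal epithelial cells and intestinal tumours of mice with or without the transcription factor Stat3 in the intestinal epithelium. The series was built to ask whether Stat3 is needed for the progression of tumours in APCmin mice, which carry a mutated Apc allele that activates WNT signalling and develop intestinal tumours. Control mice had floxed Stat3 alleles, and the Stat3-deleted mice also expressed a Cre recombinase in the intestinal epithelium. There were 6 groups of 3 arrays: control and Stat3-deleted epithelial cells (replicates 1 to 3 and 4 to 6), control and Stat3-deleted male tumours (7 to 9 and 10 to 12), and control and Stat3-deleted female tumours (13 to 15 and 16 to 18). The tumour labels call the samples colorectal tumours induced with a carcinogen and an irritant, whereas the series text describes spontaneous tumours mainly of the small intestine, so the segment of each tumour is not known. The first principal component held 69.2% of the variance and separated tumours from epithelial cells, and the lowest mean correlation of an array with its own group was 0.928, in control male tumour replicate 8.

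Stat3 was lower in every Stat3-deleted array than in every control array. Its mean log2 value was 9.83 ± 0.08 (SD, n = 3) in control and 7.87 ± 0.13 in Stat3-deleted epithelial cells, 10.11 ± 0.04 and 8.03 ± 0.25 in male tumours, and 10.15 ± 0.17 and 8.29 ± 0.20 in female tumours. The corresponding differences were -1.96, -2.09 and -1.87 (limma adjusted p 1.23e-05, 4.7e-06 and 1.24e-05). Whether the Stat3 probe set lies inside the deleted exons is not known, so this checks the labels only as far as the probes report the deletion. Xist, the RNA of the inactive X chromosome, had means of 10.03 and 10.06 in the control and Stat3-deleted female tumours and of 3.98 and 4.06 in the male ones, and the Y-linked Eif2s3y was 8.21 and 8.23 in male and 3.02 and 3.23 in female tumours. All 6 epithelial cell arrays had male values, with group means of Xist of 4.19 and 4.18 and of Eif2s3y of 8.15 and 7.59.

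**Figure D1:**
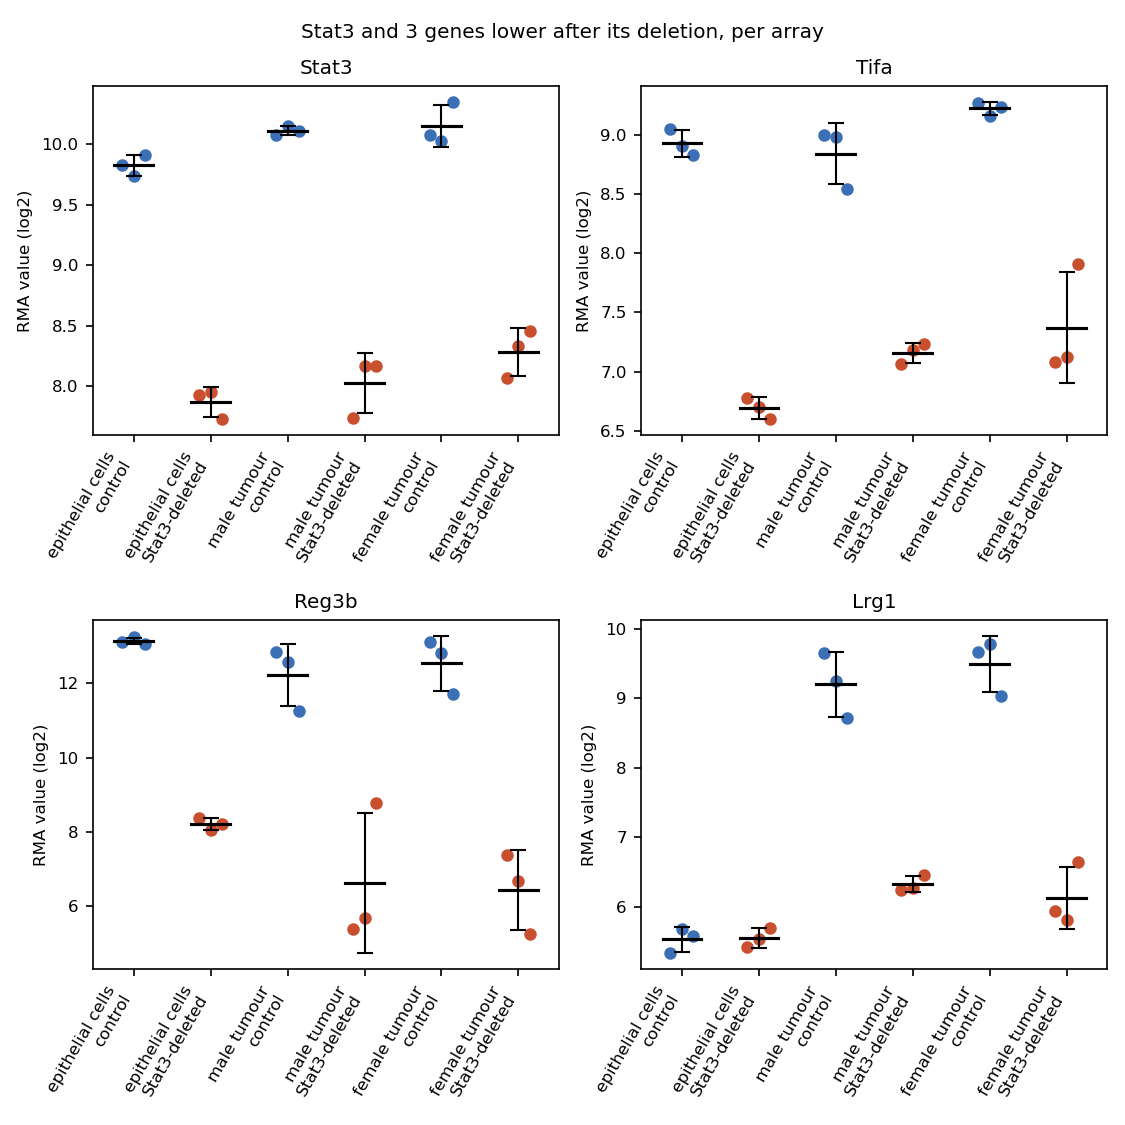
RMA values (log2, vertical axes) of Stat3, Tifa, Reg3b and Lrg1 in each of the 18 arrays, by group (horizontal axes); points are arrays, bars are group means ± SD. Stat3, Tifa and Reg3b were lower in all 3 Stat3-deleted groups, whereas Lrg1 stood at 5.53 and 5.54 in epithelial cells and was lower after deletion in tumours.

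In intestinal epithelial cells, the comparison of Stat3-deleted with control cells asks what Stat3 loss changes outside tumours. Besides Stat3, 3 genes passed, and all were lower. Reg3b, which encodes a secreted antimicrobial lectin, fell by 4.91 ± 0.71 (SE) on the log2 scale, from 13.13 ± 0.09 (SD) to 8.22 ± 0.17, a 30.1-fold difference (adjusted p 0.017). Tifa, an adaptor of innate immune signalling, fell by 2.23 ± 0.19 (adjusted p 1.99e-05), and Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, fell by 1.52 ± 0.24 (adjusted p 0.0381). Reg3g, the close relative of Reg3b, differed by -3.80 ± 0.63 and did not pass (adjusted p 0.058), although it did with only the compared groups in the fit (0.00018) and with array weights (0.00473). Among genes with a higher value, the 5 with the smallest p did not pass: Tspo 0.74, Cd226 0.84, Cst7 1.17, Themis 0.79 and Gzmk 1.03 (adjusted p from 0.166 to 0.401), the last 4 being genes of T and NK cells. All 5 passed with array weights (0.00291 to 0.0122). The weights of Stat3-deleted replicates 4, 5 and 6 were 0.30, 0.59 and 4.87. Calls made with array weights, that of Reg3g included, thus rest largely on replicate 6 in the deleted group. In all, 4 of 17316 genes passed, 0 higher and 4 lower, and 1178 had an unadjusted p under 0.05. With array weights 1134 passed, 564 higher and 570 lower, so the direction of the calls depended on the weighting. Stat3 and Tifa kept their calls in all 6 leave-one-out fits, while Reg3b (adjusted p 0.0558 to 0.129) and Kdelr3 (0.0558 to 0.372) lost theirs in each of them, so that 2 genes passed whichever of replicates 1 to 6 was left out. In these fits the Reg3b difference lay between -5.00 and -4.83, and that of Kdelr3 between -1.68 and -1.44. With only the compared groups in the fit all 4 genes passed. The main fit shares its estimate of the spread with the tumour groups. The SE of 0.71 for Reg3b thus does not measure the spread of the epithelial arrays alone.

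Of 24 measured T and NK cell markers in the epithelial cells, 0 passed over all genes and 12 were higher adjusted over the list alone. The median difference was 0.85, with Klrd1 at 1.41, Itgae at 1.29, Cd3e at 1.06 and Ccl5 at 1.53 (camera adjusted p 6.64e-16). The adjusted p was 0.327 with an estimated correlation. Stat3-deleted replicate 4 had the highest mean of these markers, 8.05 against 6.34 to 7.04 in the other 5 arrays, and without it the median was 0.39. Of 23 antimicrobial and acute-phase genes, 2 fell over all genes (Tifa and Reg3b) and 3 fell adjusted over the list alone, with a median of -0.16 (adjusted p 0.00132, and adjusted p = 0.0994 with an estimated correlation). Antigen presentation genes had a median of 0.36 and proliferation genes of 0.28 (both adjusted p 0.00132, and both adjusted p = 0.966 with an estimated correlation). Xenobiotic metabolism genes had a median of -0.47 (adjusted p 0.00224), with Gstm1 at -0.58 and Cyp1a1 at -1.08, cell adhesion genes -0.20 (0.00359) and unfolded protein response genes -0.22 (0.0116), with Atf6 at -0.61. Without Stat3-deleted replicate 4 the adhesion (-0.13, adjusted p 0.0916) and unfolded protein response lists (-0.09, 0.227) were not called, and the xenobiotic median was -0.26 (0.0373). Each of these 5 lists had 0 members past the threshold over all genes and adjusted p = 0.966 with an estimated correlation. In the STAT3 pathway list, 1 of 34 members fell, Stat3 itself, and the list was not called (median -0.01, adjusted p 0.415), with Socs1 at 0.53, Ptpn2 at -0.48 and Il6st at -0.67. Ceacam1, a cell adhesion molecule, differed by -0.85 ± 0.24 and did not pass (adjusted p 0.649).

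In male tumours, Stat3 deletion was accompanied by lower values of several antimicrobial and acute-phase genes and higher values of antigen presentation genes. Reg3b fell by 5.59 ± 0.71 (adjusted p 0.00194), Reg3g fell by 3.69 (0.0176) and Tifa fell by 1.68 (0.00055). The size for Reg3b is uncertain, because Stat3-deleted replicates 10 and 11 (5.39 and 5.70) lay below their array medians and replicate 12 stood at 8.79. Lrg1, a secreted glycoprotein of the acute phase, fell by 2.88 ± 0.25 (2.75e-05), and Serpina3n, an acute-phase protease inhibitor, fell by 3.29 (0.00363). Other large falls were in Ly6g, a neutrophil surface protein (-3.73, adjusted p 0.0128), Slc10a2, the ileal bile acid transporter (-2.60, 0.00267), the G protein subunit Gnal (-2.16) and Wfdc18 (-2.09, both 0.00342). The list of neutrophil markers was not called, and its array means overlapped (5.81 to 6.40 in control and 5.55 to 6.02 in Stat3-deleted male tumours). In the Stat3-deleted arrays Slc10a2 (3.91 to 4.61) lay near the arrays' 25th percentiles (4.37 to 4.40), so the size of its fall is uncertain. Large rises were in Ido1, an enzyme of tryptophan breakdown (2.81, adjusted p 0.0153), the class II chain H2-Eb2 (2.61, 5.17e-05), neuropeptide Npy (2.47, 0.00453) and Psmb9 and Psmb8 of the immunoproteasome (1.64 and 1.54, 0.0288 and 0.0409). H2-T10 (1.57, 0.0126), the class II regulator Ciita (1.47, 0.00363) and the interferon regulator Irf7 (1.33, 0.0288) followed.

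In total 40 genes passed in male tumours, 20 higher and 20 lower, with 1302 at an unadjusted p under 0.05. The balance of directions rested on single arrays, with 9 higher and 30 lower without replicate 8, 54 and 30 without replicate 9, and 11 and 27 with array weights. With only the 6 compared arrays in the fit, 2 passed, Stat3 and Lrg1. In that fit 681 genes had an unadjusted p under 0.05, fewer than a share of 0.05 of the tested genes. The main fit shares its estimate of the spread with the epithelial arrays, so its p-values do not rest on the spread of the tumours alone. Leaving out single arrays gave 13 genes without replicate 11, 25 without replicate 10 and 84 without replicate 9, and without replicates 9 and 15 together, a choice made after seeing the data, 117. Ido1 (adjusted p 0.135), Psmb9 (0.232), H2-T10 (0.0995), Psmb8 (0.3), Irf7 (0.24), Ly6g (0.0592) and Reg3g (0.161) lost their calls without replicate 11. Calls were also lost without replicate 10 by Ido1 (0.0657), Psmb9 (0.11), Psmb8 (0.164), Ly6g (0.0646) and Reg3g (0.0835), without replicate 7 by Psmb9 (0.0851), H2-T10 (0.0545), Psmb8 (0.115), Irf7 (0.0737) and Reg3g (0.0801), and without replicate 8 by Psmb9 (0.0663), Psmb8 (0.115), Irf7 (0.114) and Ly6g (0.0567). Of the 21 genes followed through these fits 11, Stat3 and Tifa among them, kept their calls in every leave-one-out fit.

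Of 16 antigen presentation genes, 6 rose in male tumours over all genes and 15 adjusted over the list alone, with a median of 1.14. The leading members were Ciita, Psmb9, Tap2 (1.07) and Cd74 (0.98), and leaving out any 1 of replicates 7, 8, 10 or 11 ended the calls of Tap2 (adjusted p 0.11 to 0.277) and Cd74 (0.0851 to 0.28). The list was called with the preset correlation (adjusted p 1.56e-37), with an estimated one (adjusted p = 0.0366 with an estimated correlation) and with fry (0.00652). Of 24 interferon response genes, 2 rose, Irf7 and Irf1 (0.87), and 19 rose adjusted over the list alone, with a median of 1.32, Ifit3 at 2.26 and Oasl2 at 1.85 (adjusted p 3.56e-34, and adjusted p = 0.0551 with an estimated correlation). Irf1 lost its call without any 1 of replicates 7, 8, 10, 11 or 12 (adjusted p 0.0699 to 0.373). Control replicate 8 had the lowest means of both lists, 8.31 for antigen presentation and 6.47 for interferon response. Without it the medians were 0.91 and 1.12, with 1 and 0 members past the threshold, and adjusted p = 0.213 and 0.505 with an estimated correlation. Of 34 STAT3 pathway genes, 2 fell over all genes (Stat3 and Lrg1) and 3 adjusted over the list alone, the matrix protease Mmp7 (-1.60) being the other (median -0.13, adjusted p 0.0234, and adjusted p = 0.425 with an estimated correlation). Of 23 antimicrobial and acute-phase genes, 3 fell over all genes, and adjusted over the list alone 4 fell, Retnlb (-1.61) included, and Ang4 rose (1.67), so that the list was not called (adjusted p 0.235).

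Markers of gut segments differed between the tumour arrays. Control replicates 9 and 15, 1 male and 1 female tumour, had high values of the posterior gut gene Hoxd13 (8.25 and 9.10) and of the colon carbonic anhydrase Car1 (10.90 and 10.24) and low values of Gata4, a regulator of the proximal small intestine (6.92 and 6.84). In the other 10 tumours Hoxd13 lay between 4.82 and 5.59 and Gata4 between 8.86 and 9.86. Car1 was also high in Stat3-deleted female replicate 16 (8.40), where Hoxd13 and Gata4 were not out of range, and lay between 4.36 and 5.05 in the other 9. The ileal bile acid binding protein Fabp6 was 7.92, 11.10, 8.53 and 7.18 in control replicates 7, 8, 14 and 15 and at most 4.82 in the other tumours. Slc10a2 lay between 5.28 and 7.72 in the 6 control tumours and between 3.91 and 4.62 in the 6 Stat3-deleted tumours. A difference of gut segment between the genotypes was therefore not separated from Stat3 deletion in the tumour comparisons. In male tumours 1 of 19 ileum genes fell, Slc10a2, and 3 fell adjusted over the list alone, with Fabp6 at -3.44 and Plb1 at -1.16 (median -0.28, adjusted p 0.0307, and adjusted p = 0.752 with an estimated correlation). Without control replicate 8 the ileum list was not called (median -0.08, adjusted p 0.74). Across both sexes, 0 of 22 colon genes passed and the list was not called (median -0.12, adjusted p 0.827).

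**Figure D2:**
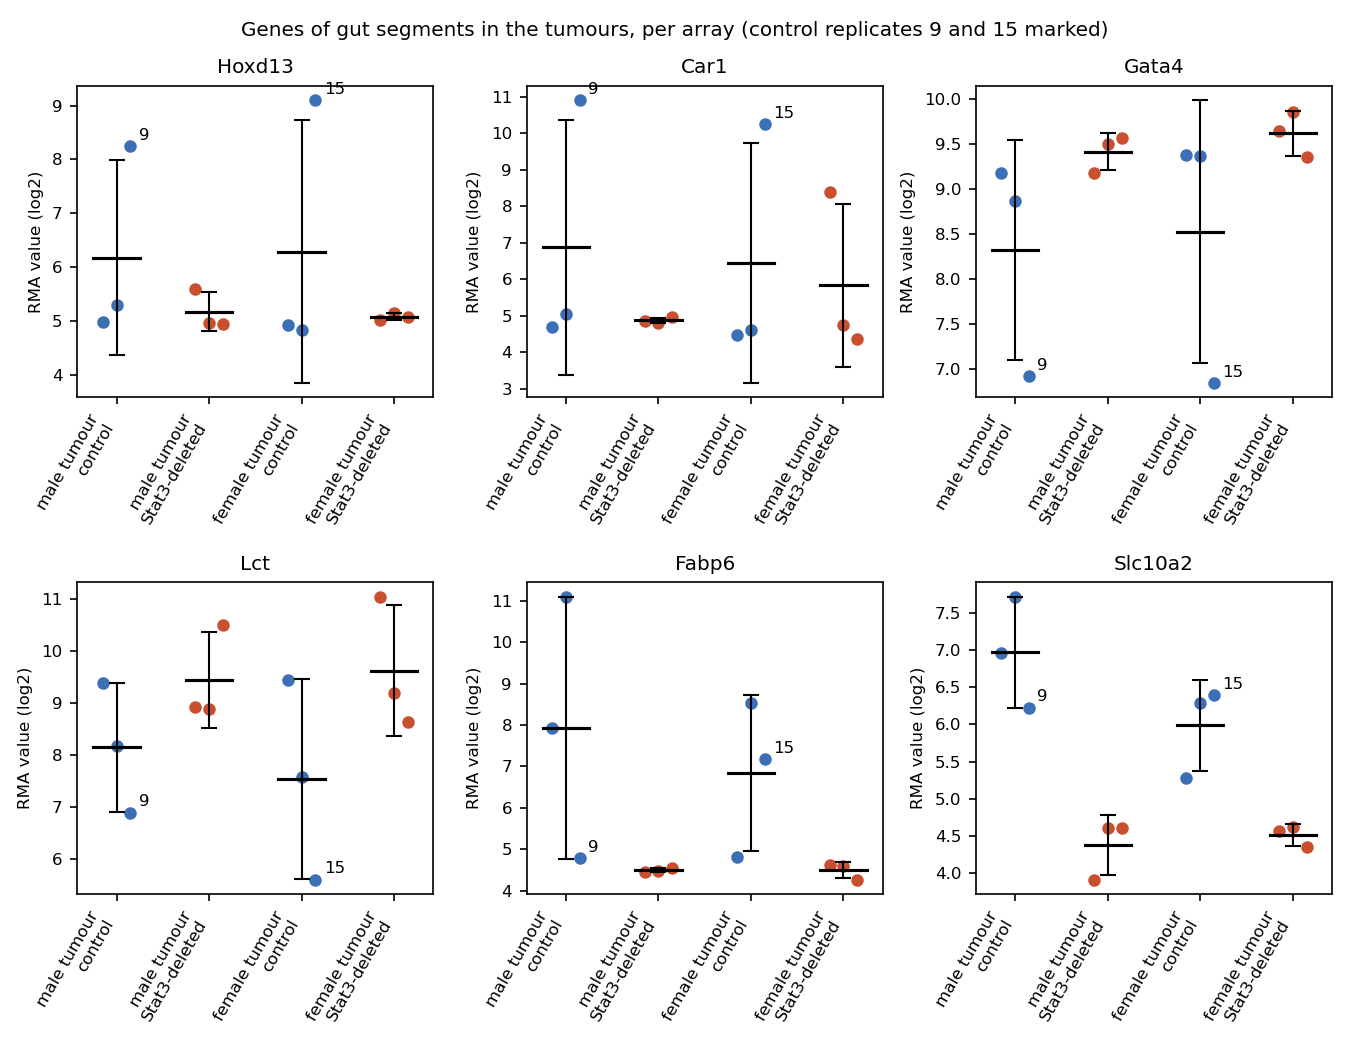
RMA values (log2, vertical axes) of 6 genes of gut segments in the 12 tumour arrays, by group (horizontal axes); points are arrays, bars are group means ± SD, and control replicates 9 and 15 are marked. Those arrays stood apart in Hoxd13 (8.25 and 9.10) and Gata4 (6.92 and 6.84) and had the highest Car1 (10.90 and 10.24), with Stat3-deleted replicate 16 next at 8.40, and Slc10a2 was higher in every control tumour than in every Stat3-deleted tumour.

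Several lists of absorptive and metabolic genes had higher medians in Stat3-deleted male tumours, with 0 members past the threshold over all genes. These were xenobiotic metabolism genes (median 0.79, adjusted p 1.67e-08, and adjusted p = 0.425 with an estimated correlation), absorptive enterocyte markers (0.87, 1.84e-07, and adjusted p = 0.752) and proximal small intestine genes (0.52, 0.00188, and adjusted p = 0.752). Without control replicates 9 and 15 these medians were 0.22, 0.04 and 0.07. Also called higher were B and plasma cell markers (0.26, adjusted p 2.46e-06, and 0.205 with an estimated correlation), tuft cell markers (0.34, 6.39e-05, and 0.425), fatty acid oxidation genes (0.26, 0.014, and 0.834), inflammatory cytokines (0.21, 0.0171, and 0.834) and unfolded protein response genes (0.12, 0.0275, and 0.752). Glycolysis and hypoxia genes were called lower (-0.25, 0.00192, and 0.539 with an estimated correlation), where Ndrg1 (-0.92) and Bnip3 (-0.78) fell adjusted over the list alone, as were fibroblast and matrix markers (-0.33, 0.0275, and 0.834). Without replicates 9 and 15 fatty acid oxidation genes (0.10, adjusted p 0.657) and fibroblast markers (-0.03, 0.483) were not called. Without replicate 8 cytokines (0.24, 0.134) and unfolded protein response genes (-0.11, 0.74) were not.

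In female tumours, the largest falls were in Reg3b, Reg3g and Lrg1. Reg3b fell by 6.09 ± 0.71 (adjusted p 0.000651), as did Reg3g (-4.63, 0.0038), Lrg1 (-3.38 ± 0.25, 5.16e-06), Serpina3n (-2.80, 0.0198), Wfdc18 (-2.44, 0.000651) and Tifa (-1.85, 0.000198). The size for Reg3b is uncertain here too, because replicate 18 (5.26) lay below its array median. The iron carrier Trf fell by 1.99 (0.0362), as did Gnal (-1.98, 0.00661), the proton channel Otop2 (-1.90, 0.00953) and Avil, an actin-binding protein of tuft cells (-1.37, 0.0447). The named rises were Npy (2.57, adjusted p 0.00451), H2-Eb2 (1.73, 0.00467) and the membrane adaptor Ank2 (0.83, 0.0437). In total 18 genes passed, 3 higher and 15 lower, with 871 at an unadjusted p under 0.05. The last count is near the share of 0.05 of the tested genes that no effect would give. With only the 6 compared arrays in the fit 0 genes passed in limma and 1438 had an unadjusted p under 0.05, the lowest adjusted p being 0.0606 for Stat3 and Lrg1. Without replicate 13 there were 10 calls and without replicate 18 there were 30. Without replicate 17 the balance turned, with 14 higher and 12 lower. Ank2 lost its call without replicate 13, 14, 15, 16 or 18 (adjusted p 0.105 to 0.215), Trf without 13, 14, 15, 16 or 17 (0.0944 to 0.233), Serpina3n without 13, 14, 16 or 17 (0.0726 to 0.142), Gnal without 13 (0.0596) or 16 (0.0564) and Otop2 without 13 (0.0802) or 16 (0.0812). Avil lost its call without any 1 of replicates 13 to 17 (0.0658 to 0.272).

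Of 23 antimicrobial and acute-phase genes in female tumours, 3 fell over all genes (Tifa, Reg3b and Reg3g), and adjusted over the list alone 7 fell and 1 rose, with Retnlb at -2.10 and a median of -0.56. This list was called with the preset correlation (adjusted p 1.29e-05), with an estimated one (adjusted p = 0.0237 with an estimated correlation) and with fry (0.00221); without control replicates 9 and 15 the median was -0.24 and adjusted p = 0.192 with an estimated correlation. STAT3 pathway genes fell in 2 of 34 cases over all genes and 6 adjusted over the list alone, with Mmp7 at -1.70 and Icam1 at -0.96 (median -0.15, adjusted p 0.000242, and adjusted p = 0.149 with an estimated correlation). Interferon response genes had a median of 0.57 (adjusted p 3.24e-06, and adjusted p = 0.569 with an estimated correlation), with Ifit3 at 1.38, and antigen presentation genes of 0.23 (0.00016, and adjusted p = 0.608), with Ciita at 0.57, and 0 members of either passed. Xenobiotic metabolism genes had a median of 0.90 (adjusted p 7.28e-16, and adjusted p = 0.149 with an estimated correlation), with Aldh1a1 at 1.88, and absorptive enterocyte markers of 0.88 (1.05e-10, and adjusted p = 0.569), with Lct at 2.09. Without control replicates 9 and 15 these medians were 0.68 and 0.17. Glycolysis and hypoxia genes had a median of -0.28 (1.05e-05, and adjusted p = 0.287 with an estimated correlation), where Bnip3 (-1.03) and the lactate transporter Slc16a3 (-0.71) fell adjusted over the list alone.

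The remaining lists called in female tumours were each lost with an estimated correlation. Fatty acid oxidation genes (median 0.38, adjusted p 1.29e-05, and adjusted p = 0.569 with an estimated correlation), mast cell markers (0.28, 8.82e-05, and 0.546), proximal small intestine genes (0.43, 0.000486, and 0.594) and enteroendocrine markers (0.18, 0.00135, and 0.569) were higher. The same held for goblet cell markers (0.14, 0.00556, and 0.662), B and plasma cell markers (0.14, 0.0128, and 0.569), tuft cell markers (0.25, 0.014, and 0.644), in which Avil fell, and enteric neuron markers (0.11, 0.0227, and 0.662). Proliferation genes (-0.24, 0.0014, and 0.76) and cholesterol synthesis genes (-0.23, 0.00516, and 0.644) were lower. Leaving out control replicates 9 and 15 gave medians of the fatty acid oxidation, proximal small intestine, enteroendocrine, goblet and enteric neuron lists of 0.18, 0.15, 0.01, -0.15 and 0.04, and all but the first lost their calls (adjusted p 0.0613 to 0.821).

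Across tumours of both sexes, 123 genes passed, 50 higher and 73 lower, with 2081 at an unadjusted p under 0.05. Reg3b fell by 5.84 ± 0.50 (adjusted p 8.31e-06), a size that is uncertain because replicates 10, 11 and 18 (5.39, 5.70 and 5.26) lay below their array medians, where dim genes cannot be told from background. Also lower were Reg3g (-4.16 ± 0.45, 0.000102), Lrg1 (-3.13 ± 0.18, 4.12e-08), Serpina3n (-3.04, 0.000102) and Ly6g (-2.99, 0.00193), while the list of neutrophil markers was not called. The receptor phosphatase Ptprz1 fell by 2.83 (0.0125), as did Wfdc18 (-2.27, 1.18e-05), Gnal (-2.07, 5.04e-05), Tifa (-1.77 ± 0.13, 2.5e-06) and Retnlb, a goblet cell product with antibacterial activity (-1.85 ± 0.28, 0.0028). Among genes whose arrays did not overlap between the groups, the largest rises were Npy (2.52, adjusted p 5.04e-05), the protease Cym (2.23, 0.00666), Asb4 (2.20, 0.0118) and H2-Eb2 (2.17, 3.68e-06). The small heat shock protein Cryab (1.03, 0.00403), the interferon-induced Ifi27l2a (1.02, 0.00145), the drug-metabolising Fmo1 (0.99, 0.00245) and Ube2l6 of the ISG15 pathway (0.91, 0.0059) followed. Each of these genes kept its call in every leave-one-out fit. With only the tumour arrays in the fit 43 genes passed, and Ptprz1 (0.107), Cym (0.0803) and Asb4 (0.106) were not among them. Leaving out single arrays gave 64 genes without replicate 16, 72 without replicate 11 and 265 without replicate 18, and 202 passed without control replicates 9 and 15. When each array was centred on its median, 165 genes passed, 45 higher and 120 lower, which moved the share of higher calls from 40.7% to 27.3%. Without replicate 17 most calls were higher (57 against 44), and without replicates 9 and 15 there were 100 higher and 102 lower.

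**Figure D3:**
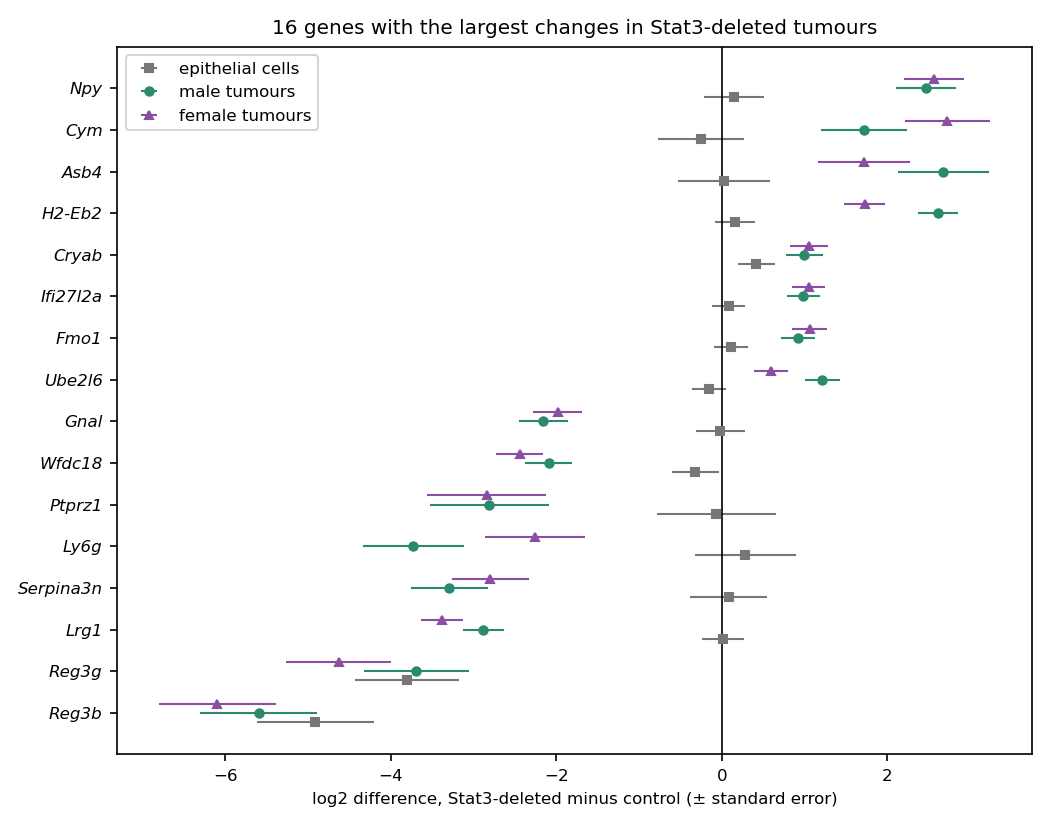
Log2 differences between Stat3-deleted and control samples (horizontal axis, ± standard error) of the 16 genes with the largest rises and falls among those whose arrays did not overlap across tumours of both sexes (vertical axis), in epithelial cells, male tumours and female tumours, with 3 arrays per group. Reg3b differed by -4.91, -5.59 and -6.09, whereas Lrg1 differed by 0.02 in epithelial cells and by -2.88 and -3.38 in tumours.

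Of 34 STAT3 pathway genes, 3 fell across tumours of both sexes, Stat3, Lrg1 and Mmp7 (-1.65 ± 0.34, adjusted p 0.0328), and 8 fell adjusted over the list alone. Mmp7 lost its call without any 1 of replicates 8, 11, 12 or 14 to 17 (0.0568 to 0.106), and with only the tumour arrays in the fit (0.0974). The list was called with the preset correlation (median -0.10, adjusted p 0.00266) and fry (0.000735), and had adjusted p = 0.171 with an estimated correlation. Socs3, the feedback inhibitor of STAT3 signalling, differed by -0.55 (adjusted p 0.145), Cebpd by -0.94 (0.0659), and neither passed. Of 23 antimicrobial and acute-phase genes, 4 fell and 1, Reg4, rose (0.65, adjusted p 0.0497), and adjusted over the list alone 7 fell and 2 rose (median -0.30, adjusted p 0.0115, and adjusted p = 0.143 with an estimated correlation). Reg4 lost its call without any 1 of replicates 8 to 18 (0.0507 to 0.14), and with only the tumour arrays in the fit (0.133). Lcn2, a neutrophil and epithelial iron-sequestering protein, differed by -1.82 and did not pass (0.0638). Of 24 interferon response genes, 4 rose, Irf7 (0.96), Ifit3 (1.82), Stat2 (0.90) and Oasl2 (1.37), and 19 rose adjusted over the list alone (median 0.96, adjusted p 4.45e-23, and adjusted p = 0.143 with an estimated correlation). Of 16 antigen presentation genes, 4 rose, Ciita (1.02), Tap2 (0.76), Psmb9 (0.98) and H2-Aa (0.79), and 14 rose adjusted over the list alone (median 0.75, adjusted p 2.92e-23, and adjusted p = 0.143 with an estimated correlation). Irf7 and Ciita kept their calls in every leave-one-out fit. Calls were lost by Ifit3 without replicate 11, 13, 14 or 16 (0.0565 to 0.0618), Stat2 without 7, 8, 10 to 14, 16 or 17 (0.0541 to 0.13) and Oasl2 without 7 or 11 to 17 (0.0511 to 0.133). The same held for Tap2 without 11 (0.0561) or 16 (0.0572), Psmb9 without 7, 10, 11 or 13 to 17 (0.0592 to 0.12) and H2-Aa without any 1 of 10 to 18 (0.0557 to 0.138). With only the tumour arrays in the fit, Ciita (0.0292) alone of these 8 genes passed, and the others had adjusted p from 0.0628 for Irf7 to 0.18 for Stat2, Oasl2, Psmb9 and H2-Aa.

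Without control replicates 9 and 15, 17 interferon response genes and 11 antigen presentation genes passed across both sexes. The medians were 1.24 and 0.92, with adjusted p = 0.0376 and 0.0361 with an estimated correlation. These arrays had the highest means of both lists among the controls of their sex (interferon response 8.18 and 8.73). Leaving them out thus raises the medians whatever made them high, and keeps replicate 8, which had the lowest means. The rise therefore decides nothing about an effect of Stat3. Without control replicate 8, 3 and 4 genes passed, with medians of 0.81 and 0.59 and adjusted p = 0.302 and 0.233 with an estimated correlation.

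**Figure D4:**
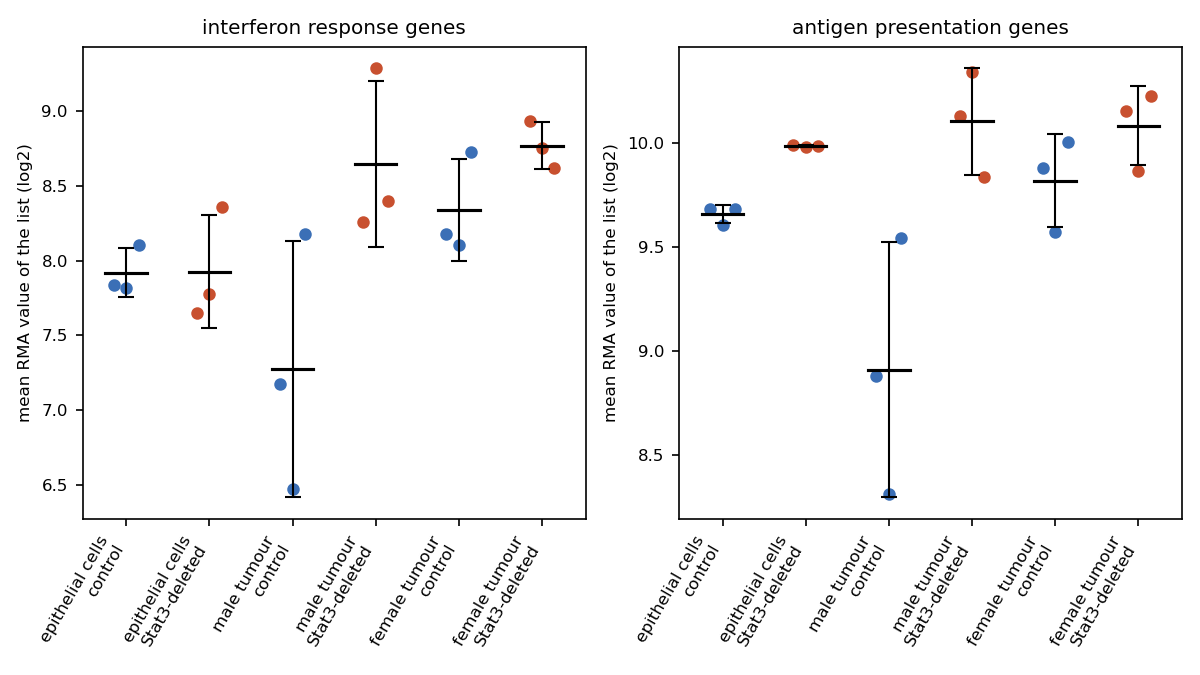
Mean RMA value (log2, vertical axes) of 24 interferon response genes and 16 antigen presentation genes in each of the 18 arrays, by group (horizontal axes); points are arrays, bars are group means ± SD. Control male tumour replicate 8 had the lowest mean of both lists, 6.47 and 8.31.

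Among metabolic and cell type lists across both sexes, Bnip3, a hypoxia-induced mitochondrial protein, fell by 0.90 (adjusted p 0.0125) as 1 of 23 glycolysis and hypoxia genes, and 8 fell adjusted over the list alone (median -0.26, adjusted p 1.79e-05, and adjusted p = 0.189 with an estimated correlation). Of 27 xenobiotic metabolism genes 0 passed over all genes and 10 were higher adjusted over the list alone (median 0.86, adjusted p 1.97e-15, and adjusted p = 0.143 with an estimated correlation), with Gstm3 at 1.18 and Ces2a at 1.45. Absorptive enterocyte markers (median 0.84, 8.91e-12, and adjusted p = 0.473 with an estimated correlation) and proximal small intestine genes (0.43, 0.000109, and 0.473) had 0 members past the threshold. Without control replicates 9 and 15 the medians of these 3 lists were 0.45, 0.05 and 0.06. Avil fell by 1.20 (adjusted p 0.00226) and was the only tuft cell marker of 17 to pass, while the list's median was 0.28 (0.000109, and adjusted p = 0.35 with an estimated correlation). Rfx6, a transcription factor of enteroendocrine cells, rose by 1.89 (adjusted p 0.0117) as the only 1 of 24 such markers (median 0.06, adjusted p 0.0153, and adjusted p = 0.713 with an estimated correlation). B and plasma cell markers (0.25, 2.01e-05, and 0.171 with an estimated correlation), fatty acid oxidation genes (0.30, 5.99e-05, and 0.473), goblet cell markers (0.14, 0.0122, and 0.847) and mast cell markers (0.16, 0.0122, and 0.673) had 0 members past the threshold. When control replicates 9 and 15 were left out, the medians of the fatty acid oxidation, goblet and enteroendocrine lists were 0.18, -0.17 and -0.05, and none was called (adjusted p 0.12, 0.233 and 0.877). Of 30 WNT target genes, Ascl2 (-0.82 ± 0.16, adjusted p 0.0202), a stem cell transcription factor, and Mmp7 fell, and the list was not called (median -0.19, adjusted p 0.0632). Ascl2 lost its call without replicate 11 (0.0598), 12 (0.0579), 15 (0.0533) or 17 (0.0573), whereas Bnip3, Avil and Rfx6 kept theirs in every leave-one-out fit. With only the tumour arrays in the fit, Ascl2 (0.122) and Rfx6 (0.106) were not called. Cell adhesion genes were not called (median -0.02, adjusted p 0.826), and Ceacam1 differed by -0.52 (0.204).

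Whether Stat3 deletion acted differently in male and female tumours was tested as the difference of the effects, on which 0 genes passed in limma. An unadjusted p under 0.05 was reached by 162 genes, fewer than a share of 0.05 of the tested genes. All genes had an adjusted p of 1. The smallest p among genes with a smaller value in females belonged to Irf1 (-0.91), Ido1 (-2.23), Cdk15 (-0.68), Psmb8 (-1.39) and Psmb10 (-0.75), and among those with a larger value to Itih5 (0.82), Scg3 (0.67), Tnp1 (0.55), Chrdl2 (0.76) and Dnajb4 (0.84). Antigen presentation genes had a median difference of -0.82 (adjusted p 5.21e-30) and interferon response genes of -0.90 (7e-19), with adjusted p = 0.0835 and 0.22 with an estimated correlation. Without control replicate 8 these medians were -0.66 and -0.50, with adjusted p = 0.748 and 0.951. Without control replicates 9 and 15 they were -1.02 and -1.06, and antigen presentation genes then had adjusted p = 0.0308 with an estimated correlation. Replicates 9 and 15 had the highest means of both lists among the controls of their sex. Without them replicates 7 and 8 remain as the male controls. The larger difference thus cannot be told apart from the choice of arrays.

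Genes whose response to Stat3 deletion differed between tumours and epithelial cells numbered 2, 1 higher and 1 lower, with 1624 at an unadjusted p under 0.05. The tumours were of both sexes and the epithelial arrays had male values, so tissue was not fully separated from sex. Lrg1 differed by -3.14 ± 0.31 (adjusted p 0.000288), since it changed by 0.02 in epithelial cells, where its level was 5.53 ± 0.18 in controls, against 9.21 ± 0.47 and 9.50 ± 0.40 in control tumours. Its epithelial values lay below the array medians and below every Stat3-deleted tumour, though above the arrays' 25th percentiles (4.51 to 4.57). A fall there may thus have gone unseen, and the background of its probe set was not measured. H2-Eb2 differed by 2.01 ± 0.30 (adjusted p 0.0402), with 0.16 in epithelial cells. Genes that did not pass were Npy (2.37, 0.123), Cyp2j9 (1.71, 0.153), Tent4b (0.94, 0.314), Ghr (0.88, 0.323), Npy2r (-1.58, 0.0514), Gnal (-2.06), Wfdc18 (-1.95) and Serpina3n (-3.13, the last 3 with adjusted p 0.123). All 8 passed with array weights (0.00151 to 0.0122), where replicate 6 (weight 4.87) outweighed replicates 4 and 5 (0.30 and 0.59) in the Stat3-deleted epithelial cells. Npy2r also passed with quantile normalisation (0.0373), centring (0.0351) and robust variance (0.0441). Without control replicates 9 and 15 Serpina3n (0.00778), Npy2r and Gnal (both 0.026) passed. Leaving out single arrays called Npy2r (without replicate 9, 13 or 18), Serpina3n (9 or 18), Gnal (8 or 14) and Npy, Cyp2j9 and Wfdc18 (18), with adjusted p from 0.0241 to 0.0488. Lrg1 kept its call in every leave-one-out fit, and H2-Eb2 lost its call when any 1 of replicates 1 to 8, 10 or 13 to 16 was left out (adjusted p 0.0518 to 0.232). Without replicate 18 there were 10 calls and without replicate 9 there were 5, and without control replicates 9 and 15 there were 8. When any 1 of replicates 1 to 6, 10, 15 or 16 was left out, 1 gene passed.

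The effects of Stat3 deletion in male and in female tumours correlated across 17316 genes with a Pearson's r of 0.671 and a Spearman's rho of 0.478. Genes are not independent replicates, so the arrays of each sex were also split in the other ways, and 2 of 162 other pairs of splits gave an r as large in size (from -0.68 to 0.68). Each pair of splits entered in both orientations, so every r occurs with both signs, and these 2 are the same division of the arrays. Control replicates 9 and 15, 1 of each sex, share colon genes, and without them r was 0.528. The sexes shared 10 lower calls (0.0173 would be shared by independent lists) and 2 higher calls (0.00347). The lower ones were Gnal, Lrg1, Reg3b, Reg3g, Serpina3n, Stat3, Tat, Tifa, Trf and Wfdc18, and the higher ones H2-Eb2 and Npy. They include the deleted Stat3 itself and come from the same fit with a shared spread per gene, so independent lists are only a rough reference. With only the compared groups in the fit 0 genes passed in female tumours, so none was shared. The effect in epithelial cells had an r of 0.03 (rho 0.025) with that in male tumours, where 144 of 162 other pairs of splits were as large, and of -0.144 (rho -0.234) with that in female tumours, where 24 of 162 were. Stat3, Reg3b and Tifa were called lower in all 3 settings.

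Control tumours were compared with control epithelial cells to describe the tumour tissue, with tissue and preparation confounded. Sex was confounded in part as well, since the epithelial arrays had male values and the tumours were of both sexes. Genes of WNT signalling, stem cells, cell division and stroma were higher, and genes of absorption and detoxification lower. Of 30 WNT target genes, 23 rose and 1 fell (median 2.45, adjusted p 6.92e-09), with Cd44 at 3.57, Sox9 at 2.32, Prox1 at 5.07 and Nkd1 at 4.06. Of 21 stem cell markers 19 rose (median 2.03, 1.18e-08), Clu (5.66 ± 0.18), Anxa1 (5.70) and Znrf3 (2.60) among them, and all 33 proliferation genes rose (1.52, 5.62e-10). These 3 lists had adjusted p = 0.507, 0.328 and 0.539 with an estimated correlation. The enterocyte markers fell in 28 of 28 cases (median -2.48, adjusted p 4.8e-07), with the glucose transporter Slc2a2 at -4.33 and lactase, Lct, at -4.46, and xenobiotic metabolism genes in 23 of 27 (-2.60, 1.98e-06), with Ces2a at -3.94 and Cyp1a1 at -3.49. These 2 lists had adjusted p = 0.562 and 0.539 with an estimated correlation.

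Stromal, endothelial and macrophage markers were higher in tumours, whereas the other immune lists were not called. Fibroblast and matrix markers rose in 22 of 25 cases (median 2.57, adjusted p 1.51e-08), with Pdgfra at 3.83 and Col1a1 at 4.07, endothelial markers in 17 of 18 (1.44, 1.83e-08), smooth muscle markers in 12 of 17 (1.47, 0.000588) and macrophage and dendritic cell markers in 18 of 22 (1.43, 5.86e-05). Genes of epithelial-mesenchymal transition and invasion rose in 19 of 28 cases (1.66, 1.41e-06), with the matrix proteases Mmp14 at 3.23 and Mmp10 at 4.63. With an estimated correlation these 5 lists had adjusted p = 0.531, 0.328, 0.562, 0.562 and 0.507. Cholesterol synthesis genes rose in 12 of 17 cases (1.06, 0.000433, and 0.539 with an estimated correlation) and glycolysis and hypoxia genes in 12 of 23 (0.47, 0.0236, and 0.562), with the glucose transporter Slc2a1 at 2.51. Enteroendocrine markers fell in 19 of 24 cases (-1.03, 3.04e-05, and 0.531 with an estimated correlation), proximal small intestine genes in 13 of 18 (-1.35, 0.00443, and 0.562) and ileum genes in 14 of 19 (-1.37, 0.0051, and 0.539).

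Among the largest single differences were higher values in tumours of Lcn2 (5.78), Anxa1, Clu, Wfdc18 (5.62), the amino acid transporter Slc38a4 (5.56), Serpina3n (5.40), Prox1 and Igfbp5 (5.05). Large falls were Slc5a12 (-4.72), Cyp2c29 (-4.62), Lct, Tmprss15 (-4.45), Slc5a4a (-4.38), Slc2a2, Enpp7 (-4.28) and Cyp3a11 (-4.15), among them transporters and digestive enzymes of the brush border (adjusted p for these 16 from 1.13e-11 for Clu to 0.000987 for Cyp3a11). In total 11373 of 17316 genes passed, 5258 higher and 6115 lower, of which 2438 and 1003 changed at least 2-fold. The median difference of all genes was -0.08, and -0.14 after quantile normalisation.

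**Figure D5:**
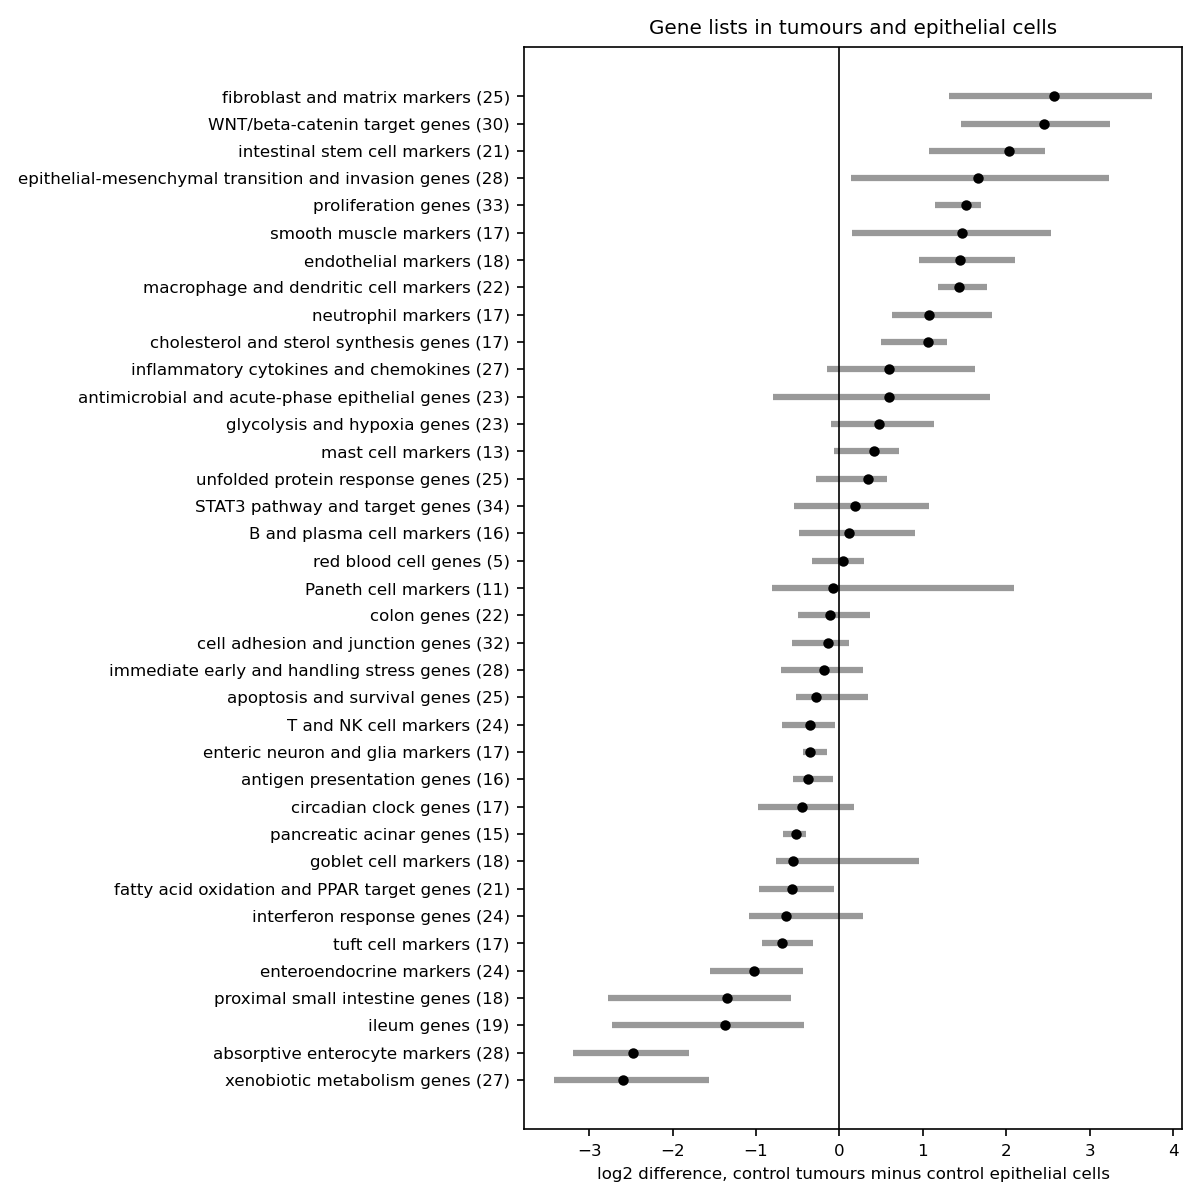
Log2 difference between control tumours (6 arrays) and control epithelial cells (3 arrays) for 37 gene lists (vertical axis, number of measured members in brackets); points are medians over members and bars the middle range from the 25th to the 75th percentile. Fibroblast, WNT and stem cell lists had medians of 2.57, 2.45 and 2.03, and enterocyte and xenobiotic metabolism lists of -2.48 and -2.60.

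Male and female tumours, averaged over genotypes, differed in 4 genes, all sex-linked, with 1061 at an unadjusted p under 0.05. Eif2s3y (5.09, adjusted p 6.32e-12), Uty (3.96) and Kdm5d (2.80) were higher in males and Xist (-6.02, 2.48e-14) lower. Genes that did not pass included Pdpn (-1.0, 0.149), Phf11a (-0.67, 0.304, but 0.0357 with array weights), Kdm5c (-0.61) and Tnfrsf9 (-1.03, both 0.345), and Dbp (0.92) and Prp2 (0.68, both 0.749). Immune gene lists had lower medians in males: antigen presentation (-0.41, adjusted p 1.41e-10), interferon response (-0.58, 5.82e-10), macrophage and dendritic cell markers (-0.45, 1.48e-06) and inflammatory cytokines (-0.38, 4.75e-07), with adjusted p = 0.561 with an estimated correlation for each and 0 members past the threshold. Control male replicate 8 had the lowest interferon and antigen presentation means. Female replicates 15 and 18 had the highest means of cytokines (7.80 and 7.25, against 6.35 to 6.57 in the other females) and of macrophage and dendritic cell markers (8.25 and 8.09, against 6.95 to 7.32). With the preset correlation 21 of 37 lists were called, and with an estimated correlation 0 were.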

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

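The tests without control replicates 9 and 15, without replicate 8 and without replicate 4 were chosen only after the results were seen, and the reading of the last pair against the spread of their genes was added after their values were known. The results below were singled out because the effect of Stat3 deletion differed between the sexes or between tumours and epithelial cells in a test of the difference itself. Groups of 3 are too small for a test of single arrays that stand apart. The ± values beside medians below are the SD over genes divided by the square root of the number of genes. Genes on the same arrays are not independent, so these values do not measure the spread between samples.

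Between the sexes, as the female minus the male effect in tumours, 14 lists differed with the preset correlation and 0 with an estimated one. Medians were below 0 for antigen presentation genes (-0.82), interferon response genes (-0.90), proliferation genes (-0.28), inflammatory cytokines and chemokines (-0.38), cholesterol synthesis genes (-0.30), antimicrobial and acute-phase genes (-0.49), B and plasma cell markers (-0.19) and T and NK cell markers (-0.13). They were above 0 for fibroblast and matrix markers (0.25), cell adhesion genes (0.18), circadian clock genes (0.31), mast cell markers (0.34), ileum genes (0.38) and enteric neuron and glia markers (0.10). With an estimated correlation the adjusted p lay between 0.0835, for antigen presentation genes, and 0.834, for T and NK cell markers.

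Between tissues, as the tumour minus the epithelial effect, 15 lists differed with the preset correlation and 0 with an estimated one, where the adjusted p was 0.738 or higher. Medians were above 0 for xenobiotic metabolism genes (1.30), absorptive enterocyte markers (1.0), interferon response genes (0.96), proximal small intestine genes (0.60), fatty acid oxidation genes (0.47), antigen presentation genes (0.41), tuft cell markers (0.33), unfolded protein response genes (0.27), enteroendocrine markers (0.27) and cell adhesion genes (0.22). They were below 0 for T and NK cell markers (-0.72), proliferation genes (-0.35), WNT target genes (-0.23), stem cell markers (-0.21) and glycolysis and hypoxia genes (-0.18). The genes were H2-Eb2 (2.01, adjusted p 0.0402), higher after deletion in tumours, and Lrg1 (-3.14, adjusted p 0.000288), lower after deletion in tumours. Lrg1 lay between 5.33 and 5.69 in the epithelial cells, below the array medians and below every Stat3-deleted tumour. A fall there may thus have gone unseen, and its difference does not show that Stat3 acted differently.

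Enterocyte, proximal small intestine and xenobiotic metabolism genes had a median of 0.77 over 68 members in Stat3-deleted against control tumours. Less epithelium in the control tumours is argued against by 17 pan-epithelial genes, whose median was -0.03 ± 0.04 (SE over genes). Control replicates 9 and 15, with colon genes, may come from another gut segment than the other tumours. Their Hoxd13 was 8.25 and 9.10, against at most 5.59 in the other tumours. Without them the median was 0.20 ± 0.06, and xenobiotic metabolism genes kept a median of 0.45 of 0.86. This fall cannot decide for a difference of segment. The same arrays had the lowest enterocyte means of the tumours (8.25 and 8.01, against at least 9.51 in the others). Leaving them out thus lowers the median whatever made them low. An effect of Stat3 on differentiation, which the design names, was not separated from the segment of the tumour.

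Interferon response and antigen presentation genes had a median sex difference of -0.85 over 40 members, the effect being larger in males. Fewer immune cells in the male control tumours are argued against by 16 pan-leukocyte genes, whose median in males was 0.14 ± 0.05 against 1.24 for the lists. Control male replicate 8 alone cannot be told apart from the pattern, because without it the difference was -0.57 ± 0.05, which lay at the bound set for no effect of that array and was not past it by its spread. Sex, which the design names, stays open and was not separated from that array.

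T and NK cell markers had a median of 0.85 over 24 members in Stat3-deleted against control epithelial cells. A larger share of lymphocytes in the Stat3-deleted preparations may account for it, since 16 pan-leukocyte genes, none of them on the marker list, had a median of 0.76 ± 0.09, with Coro1a at 7.88 against 6.72 and Laptm5 at 8.29 against 7.25 on the log2 scale. Replicate 4 alone cannot be told apart from the pattern, because the median without it was 0.39 ± 0.07, within the spread of the bound set for a cause. Whether more lymphocytes lay in the epithelium of these mice or were carried over in the isolation was not tested.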

How the results depend on the processing

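The fits without control replicates 9 and 15 and the list tests without replicate 8 were chosen only after the results were seen. Counts of genes that moved by over 1.5 times are given here, and for the differences between settings the cause was not tested unless stated. With all probe sets tested, 7 passed for epithelial cells against 4, 1 against 2 for the difference between tissues, and 9 against 4 for male against female tumours. With array weights, which ranged from 0.16 (replicate 8) to 4.87 (replicate 6), 1134 genes passed for epithelial cells, 745 for female tumours, 1414 for both sexes and 1038 for the difference between tissues. With only the compared groups in the fit, 2 passed for male tumours, 0 for female tumours and 43 for both sexes. In limma 681 and 1438 genes had an unadjusted p under 0.05 for male and female tumours, against 1302 and 871 in the main fit. For epithelial cells 6 passed against 4, within 1.5 times. That fit estimates the spread from fewer arrays and from the compared groups alone, and which of these moved the counts was not tested. Without replicates 9 and 15, 117 passed for male tumours, 202 for both sexes and 8 for the difference between tissues. Leaving out single arrays gave 2 for epithelial cells, 13 to 84 for male tumours (without replicates 11 and 9), 10 to 30 for female tumours (13 and 18), 64 to 265 for both sexes (16 and 18) and 1 to 10 for the difference between tissues. The count for the difference between the sexes was 0 in all alternatives, and those for tumours against epithelial cells stayed within 1.5 times.

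Of the lists called with the preset correlation, an estimated correlation left 0 of 7 for epithelial cells, 1 of 14 for male tumours, 1 of 17 for female tumours, 0 of 14 for both sexes, 0 of 14 and 0 of 15 for the differences between sexes and tissues, 0 of 15 for tumours against epithelial cells and 0 of 21 for male against female tumours. In the same order fry called 1, 3, 2, 5, 0, 0, 27 and 0. Without replicate 8, 8 lists differed between the sexes. The difference of the Stat3 change between tissues lay near 0 (-0.02) and changed sign, without passing, with centred arrays (0.008), array weights (0.109), without replicates 9 and 15 (0.028) and without replicate 2 (0.022), 4 (0.012), 5 (0.022), 10 (0.052), 15 (0.029) or 16 (0.034), among a range over single arrays of -0.093 to 0.052. Of 714 pairs of a gene and an alternative for both sexes, 631 kept direction and side of the threshold and 83 lost the call, and of 3302 for tumours against epithelial cells 3264 did and 35 lost it. For male tumours 248 of 315 did and 67 lost the call, and for female tumours 169 of 210 and 41. For the difference between tissues 1 of 2 calls was higher, and with quantile normalisation, centring or robust variance, which each added 1 lower call, 1 of 3 was.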

Other observations

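No test in this part was chosen after its result was seen, and the counts of other splits were planned. Several gene groups had members that passed between control tumours and control epithelial cells although their lists were not called as wholes, and in most of them members went in both directions. Of 34 STAT3 pathway genes, 13 rose and 9 fell (median 0.19, camera adjusted p 0.251), the cytokine receptors Osmr (2.52) and Il6st (1.87), Lrg1 (3.83) and Myc (2.73) leading the rises. Of 23 antimicrobial and acute-phase genes, 11 rose and 5 fell (0.60, adjusted p 0.178), with Lcn2 at 5.78, Pla2g2a at 4.63 and Saa3 at 4.56. Of 24 interferon response genes, 5 rose, the chemokines Cxcl9 (3.54) and Cxcl10 (2.49) and the GTPase Iigp1 (3.66) among them, and 12 fell, with Irf7 at -1.40 (-0.64, adjusted p 0.208). Antigen presentation genes fell in 5 of 16 cases (-0.38, 0.177), with Psmb10 at -0.74. Of 17 neutrophil markers 12 rose and 3 fell (1.08, 0.0578), with Ly6g at 4.24 and Il1b at 2.81, and of 27 cytokines and chemokines 11 rose and 3 fell (0.60, 0.0771), with the prostaglandin synthase Ptgs2 at 3.84.

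Epithelial cell types differed as well. Of 18 goblet cell markers 6 rose and 8 fell (median -0.56, adjusted p 0.478), with Clca1 at -2.92 and Creb3l1 at 1.53. Of 17 tuft cell markers 11 fell and 1 rose (-0.69, 0.0578), the riser being Avil (2.68), which fell after Stat3 deletion in tumours. Of 11 Paneth cell markers 4 rose and 1 fell (-0.08, 0.251), with Habp2 at 3.60 and Mmp7 at 3.08. Of 17 circadian clock genes 9 fell and 2 rose (-0.45, 0.0771), with Dbp and Nr1d1 both at -2.26 and Per2 at -1.40; sampling times are not in the labels. Handling stress genes rose in 6 and fell in 11 of 28 cases (-0.19, 0.283), with Fosb at -1.76 and Ier3 at 2.27. T and NK cell markers fell in 8 of 24 cases and 1 rose (-0.35, 0.168), with Gzma at -2.05, and B and plasma cell genes rose in 7 and fell in 5 of 16 (0.12, 0.282), with Jchain at 4.31.

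The arrays were also divided in other ways than by the labels, and the counts of genes and lists were made again. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 4 genes in epithelial cells against at most 1 in the others, 40 against 2 in male tumours and 18 against 0 in female tumours, so that 1 of 10 splits, the real one, reached the real count in each. For lists with the preset correlation the real and highest other counts were 7 and 8 (3 splits as large), 14 and 24 (5) and 17 and 22 (6). For both sexes 3 of 100 splits, the real one among them, reached 123 genes, a share under 0.05. The highest other split called 556, several times as many, which points to another structure of the samples, so the count does not exclude chance. That split parted the tumours along the second principal component. It lay from -0.59 to 39 in replicates 8, 9, 10, 14, 15 and 18, and from -27.4 to -5.46 in the other tumours. The source of that structure was not tested. For the difference between tissues 2 of 100 splits reached the 2 genes, the real one among them (highest other 2). These splits mix control and Stat3-deleted arrays within each tissue, so they test for no effect in any tissue. Whether the effect differs between tissues is not decided by them. For tumours against epithelial cells 1 of 84 splits, the real one, reached 11373 (highest other 8736, median of the others 0), so chance is excluded there. The split with 8736 calls kept epithelial replicates 1 to 3 together under a tumour label. It thus still held part of the tissue difference.

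For the difference between the sexes 0 genes passed, so that all 100 of 100 splits reached the count by its nature and nothing follows from it (highest other 248). The count of 4 in male against female tumours was reached by 9 of 100 splits (highest other 473), so the number of calls alone excludes nothing. The 4 genes themselves, Xist, Eif2s3y, Uty and Kdm5d, parted all 6 male from all 6 female tumours (adjusted p 2.48e-14 to 3.9e-07) and kept their calls in every leave-one-out fit, so chance is excluded for them. For male against female tumours the highest other count was many times the real one, which again points to an untested structure of the samples. The counts of lists called with the preset correlation were reached often by other splits: 14 for both sexes by 62 of 100 (highest other 26), 14 for the difference between the sexes by 61 of 100 (26), and 15 for the difference between tissues by 27 of 100 (23). For tumours against epithelial cells 15 lists were reached by 57 of 84 splits (26), and for male against female tumours 21 by 19 of 100 (27). Chance is thus not excluded for any of these list counts.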
